A study of Homo sapiens with 6 samples.

How the data were processed

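RNA of H1 human embryonic stem cells, trophoblast stem cells and syncytiotrophoblast was measured by poly-A selected RNA sequencing, with 2 wild-type samples in each of 3 groups. The deposited table held whole-number read counts for 58243 Ensembl genes in 6 columns, 1 per sample, and all columns were used. Per the submitters' processing notes, STAR, SAMtools, Subread and featureCounts were used with genome build hg38. Their versions and settings, the annotation release, the strand setting, the handling of reads with several matches and any filter applied to the table are not given in the sources used here. The series text speaks of H2AJ knockdown and ribosomal RNA depletion, whereas the labels of these 6 samples name wild-type cells and poly-A selection, and the sample labels were followed. Without the strand setting, values of antisense genes and of genes that overlap others on the opposite strand are uncertain.

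Of the gene identifiers, 42284 had a symbol in the reference used here and 57980 were found in GENCODE release 29, which supplied the coordinates; 263 were in neither. No read was counted for 26429 genes. Total counts ran from 15421558 to 20289222 per library. A count of 3 over both libraries of a group corresponds to 0.0796 CPM in ESC, 0.0721 in TSC and 0.101 in STB, and a fold against a group at 0 was computed against that floor. For a group with 1 to 3 counts the ratio is given with an exact 95% interval. Intervals and floors cover counting error only.

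Genes were filtered with filterByExpr, which left 18036, scaled by TMM and fitted by the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with a coefficient per group over all 6 samples and 3 residual degrees of freedom. The contrasts were TSC against ESC, STB against TSC and STB against ESC, and p-values (2-sided) were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.115. The standard error is the absolute log2 fold change over the square root of the F statistic. For a gene with few counts in a group it understates the error of the fold change. It is therefore left out for the ESC to TSC changes of POU5F1 and COL3A1. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over 63 tests, being 21 lists in 3 contrasts; lists with fewer than 5 tested members had no set test. The recovery of known changes was tested on simulated data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

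The 22 gene lists, the tests, the contrasts, the rule for named genes and most alternatives were chosen before the data were examined. The lists were core and primed pluripotency, naive pluripotency, trophoblast stem cell and cytotrophoblast, syncytiotrophoblast, pregnancy-specific glycoproteins, extravillous trophoblast, amnion, mesoderm, endoderm, neural ectoderm, fibroblast and mesenchyme, replacement H2A variants, replication-dependent H2A, histone chaperones and H3.3, DNA methylation, cell cycle, p53 targets and cell cycle arrest, senescence-associated secretion, cholesterol synthesis and uptake, hypoxia response, imprinted genes and interferon response. Of 434 list members 5 had no match in the table. Named genes were the tested replacement H2A variants; in each contrast the 6 largest called increases and the 6 largest called decreases without overlap between replicates and with at least 20 CPM in the higher group, among genes with a symbol; and for each list up to 3 called members with the smallest adjusted p, plus the called member with the smallest adjusted p that went against the majority. Names outside the rule are the members that went against their list, such as BCAM, VIM, TAGLN and ACTA2, the genes said to be named after their values were seen, the most counted genes, and the genes of the lists added later.

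Alternatives were DESeq2 1.42.0 with its own size factors, DESeq2 size factors or total counts only in edgeR, no filter on low counts, a mean of at least 1 CPM, a required 2-fold change, only the groups compared, a robust spread estimate, the replicate number as a block, an estimated correlation or fry for the lists, and leaving out each sample in turn. With a sample left out, its group's remaining sample was assumed to vary like the other groups. Offsets for transcript GC content and length, and leaving out the mitochondrial genes, were alternatives chosen after seeing the data.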

Results

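Poly-A selected RNA was sequenced from H1 cells, an established line of human embryonic stem cells, in 3 states. The states were primed embryonic stem cells (ESC), trophoblast stem cells derived from them (TSC), and syncytiotrophoblast (STB), the fused hormone-secreting layer of the placenta. There were 6 wild-type samples, 2 per state. The total count per library was 18003806 and 18429126 in ESC, 20167198 and 20289222 in TSC, and 15421558 and 16228915 in STB. Group levels are in CPM, the usual library-scaled read count, after TMM scaling, given as mean ± SD of n = 2 libraries. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples.

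The first principal component held 76.3% of the variance and mainly parted ESC from TSC and STB. The second held 18.5% and mainly parted TSC from STB. EEF1A1, an elongation factor of protein synthesis, was the most counted gene in ESC, with 1.54% and 1.47% of counts, and the matrix protein gene FN1 took that place in STB, with 2.19% and 1.92%. Mitochondrial transcripts made up 1.08% and 1.22% of counts in ESC, 2.59% and 5.29% in TSC, and 2.47% and 2.68% in STB. The TSC libraries differed from each other more than the other pairs did. The median absolute log2 difference between replicates was 0.26 in TSC, 0.14 in ESC and 0.17 in STB. Between the TSC libraries, the differences of single genes followed transcript GC content and length, which accounted for 21.4% of their variance across genes.

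The series title names the histone variant H2A.J. Its gene, H2AJ (ENSG00000246705), lies on chromosome 12 from 14774383 to 14778002 on the plus strand of GRCh38, with no other annotated gene over it. H2AJ was at 29.8 ± 3.75 CPM in ESC, 31.1 ± 12.1 in TSC and 62.0 ± 0.809 in STB. It rose 1.99-fold from TSC to STB (log2 fold change 0.99, SE 0.21, adjusted p = 0.00107) and stood 2.08-fold higher in STB than in ESC (1.05, SE 0.21, adjusted p = 0.00037). Both STB libraries lay above all 4 others. From ESC to TSC no change was called (0.06, SE 0.21, adjusted p = 0.81), and that result rested on single TSC libraries. These held 39.7 and 22.5 CPM of H2AJ. Without TSC replicate 1 the log2 fold change was -0.41 (adjusted p = 0.0158), and without TSC replicate 2 it was 0.42 (adjusted p = 0.0074). The STB against TSC value was 0.64 without TSC replicate 2 and 1.46 without TSC replicate 1. With offsets for transcript GC content and length, chosen after seeing the data, it was 0.76 (adjusted p = 0.000161). With the same offsets the value was 0.95 for STB against ESC (adjusted p = 9.47e-06) and 0.19 for TSC against ESC (adjusted p = 0.229).

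The other replacement H2A variants, which are made outside S phase as well, took different courses. H2AZ1 (ENSG00000164032, chromosome 4, 99948086 to 99950388), encoding the H2A.Z found at promoters, fell at each step, from 508 ± 2.55 CPM in ESC to 231 ± 0.303 in TSC and 108 ± 4.32 in STB. Its log2 fold changes were -1.14 (SE 0.10, adjusted p = 2.01e-07) and -1.10 (SE 0.10, adjusted p = 7.61e-07). H2AX (ENSG00000188486, chromosome 11, 119093854 to 119095467), whose protein marks DNA breaks when phosphorylated, fell from 243 ± 7.0 CPM in ESC to 105 ± 19.3 in TSC (-1.21, SE 0.14, adjusted p = 2.74e-06). Its level in STB was 102 ± 12.8 CPM (STB against TSC -0.04, SE 0.14, adjusted p = 0.827), and with GC and length offsets this fall was called (-0.30, adjusted p = 0.0162). H2AZ2 was at 95.8, 92.6 and 84.5 CPM in ESC, TSC and STB and MACROH2A1 at 134, 143 and 131, with no call in any comparison. Without TSC replicate 2, MACROH2A1 was called from ESC to TSC (0.26, adjusted p = 0.0187) and from TSC to STB (-0.29, adjusted p = 0.0109), and with total counts only H2AZ2 was called from ESC to STB (-0.33, adjusted p = 0.019). MACROH2A2 was at 28.9, 31.8 and 37.2 CPM. Its STB against ESC difference was called (0.36, SE 0.15, adjusted p = 0.0393), and that call was lost without ESC replicate 1 (adjusted p = 0.135), without ESC replicate 2 (0.188), without STB replicate 1 (0.244) and without STB replicate 2 (0.0534). It was also lost with total counts only (adjusted p = 0.201), no filter on low counts (0.0987), DESeq2 (0.0916) and the replicate block (0.0597). Its STB against TSC difference was called without TSC replicate 1 (0.36, adjusted p = 0.038). Of the 6 tested members of the replacement H2A variants list, 0 rose and 2 fell from ESC to TSC (set test adjusted p = 0.42), and 1 rose and 1 fell from TSC to STB (0.892). Adjusted over the list alone, the counts were the same in both comparisons.

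**Figure D1:**
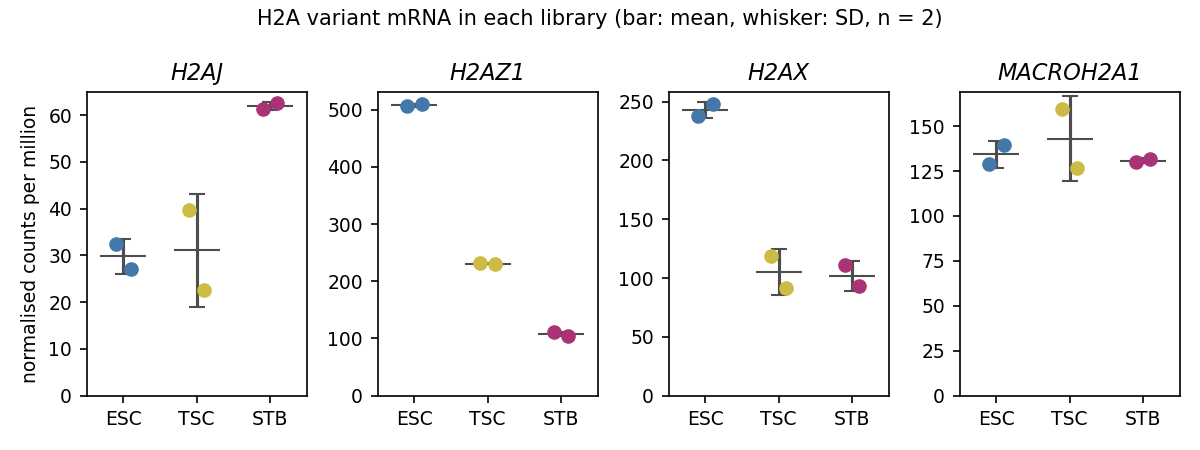
TMM-normalised CPM of replacement H2A variant genes in the 6 libraries, with points for libraries and bars for group means. H2AJ had its highest mean in STB (62.0 CPM), while H2AZ1 fell from 508 to 108 CPM between ESC and STB.

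The first comparison asked how TSC differed from the ESC they came from. Core and primed pluripotency genes fell, and most of the trophoblast, amnion, fibroblast and arrest genes tested rose. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) encodes the pluripotency factor OCT4. It fell from 2203 ± 74.5 CPM in ESC to 0.120 ± 0.0343 in TSC (log2 fold change -14.08, adjusted p = 3.81e-14). A count of 3 over both TSC libraries would be 0.0721 CPM, so the size of this fold is uncertain. NR2F2, a nuclear receptor of early trophoblast, rose from 1.33 ± 0.392 to 288 ± 25.7 CPM (7.76, SE 0.18, adjusted p = 4.37e-13). KRT8, a keratin of simple epithelia, rose 16-fold from 385 ± 3.96 to 6165 ± 553 CPM (4.0, SE 0.10, adjusted p = 1.18e-12).

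Of 18036 genes tested, 6113 were higher and 5713 lower in TSC, 65.57% in all. Requiring a change of at least 2-fold left 4184 and 3117. In a test on simulated data with this design, 17318 genes were fitted, of which 67 were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Of these 44.8%, 88.1% and 100% were recovered, with 15 false calls. The changed genes were drawn only from well-counted genes, so recovery among genes with few counts was not tested. With so few changed genes, neither the recovered shares nor the false share carry over to the real comparison. Gene list p-values are from camera with a preset correlation of 0.01. None of the 31 list calls held with a correlation estimated from the data. That setting also cuts the test to 3 residual degrees of freedom, which by itself weakens every call. The estimated correlation was 0.0139 for pluripotency, near the preset value, and 0.447 for cell cycle. For pluripotency the lost call therefore does not by itself show that correlation between genes undid it. For cell cycle, and for replication-dependent H2A at 0.409, the estimate lay far above the preset value. If those estimates hold, the preset test overstates the calls of these lists.

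All 28 tested members of the core and primed pluripotency list fell (median log2 fold change -5.86, or -5.66 with genes at 0 set to their bound). The adjusted p was 5.89e-15, and the adjusted p = 0.135 with an estimated correlation. Adjusted over the list alone, 28 fell as well. TDGF1, a NODAL co-receptor, fell from 718 ± 1.89 to 0.0960 ± 0.0677 CPM. The long non-coding RNA ESRG had 1080 ± 19 CPM in ESC and no count in TSC, at least 14982-fold lower. Naive pluripotency genes, which belong to an earlier state than primed cells, were split, with 3 higher, 3 lower and 1 not called of 7 (adjusted p = 0.892; the median, 0.19, and the test differ in sign, with a mean of -2.08), and the same counts adjusted over the list alone. KLF5 rose from 1.38 to 36.6 CPM and KLF4 from 2.76 to 10.3, both also expressed in epithelia, while FGF4 went from 2.67 CPM to no count.

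Among 28 tested trophoblast stem cell and cytotrophoblast genes, 23 rose, 2 fell and 3 were not called, also when adjusted over the list alone (median 3.63, adjusted p = 8.16e-08, and adjusted p = 0.135 with an estimated correlation). GATA3, a transcription factor of trophoblast specification, stood at 112 ± 4.12 CPM in TSC against 1 count in ESC, a ratio of 4228 (95% counting interval 758.5 to 167040). HAND1 had 148 ± 13.2 CPM in TSC and no count in ESC, at least 1857-fold higher. TEAD4, a trophectoderm factor, fell from 74.8 ± 5.52 to 31.4 ± 6.65 CPM (-1.25, SE 0.16, adjusted p = 8.66e-06), and BCAM fell too. Levels of ELF5, a factor of placental trophoblast stem cells named after its values were seen, were 0.288 and 0.0963 CPM in the TSC libraries.

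The syncytiotrophoblast list, with 25 of 44 members tested, had 15 higher, 3 lower and 7 not called in TSC, also when adjusted over the list alone (median 2.08, adjusted p = 0.0082, and adjusted p = 0.231 with an estimated correlation). This list call was lost without TSC replicate 1 (adjusted p = 0.0593) and with no filter on low counts (0.0527). PAPPA, a placental protease, rose from 2.28 ± 0.328 to 117 ± 12.5 CPM, and TBX3 from 0.529 ± 0.218 to 57.5 ± 0.901. HSD11B2, the enzyme that inactivates cortisol, fell from 44.9 ± 4.99 to 0.697 ± 0.0358 CPM. Only 3 pregnancy-specific glycoprotein genes could be tested, too few for a set test, and all 3 rose, also when adjusted over the list alone. PSG4, the highest, reached 3.68 CPM.

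Markers of other tissues also moved. Of 17 tested amnion genes 16 rose and CTSV fell, also when adjusted over the list alone (median 5.55, adjusted p = 1.68e-07, and adjusted p = 0.135 with an estimated correlation). GABRP, a GABA receptor subunit, rose 127-fold from 3.21 ± 0.523 to 408 ± 18.9 CPM, and TNC, a matrix glycoprotein, from 16.4 ± 1.14 to 1353 ± 23.2. Of 14 fibroblast and mesenchyme genes 13 rose and THY1 fell, from 305 ± 7.47 to 76.3 ± 0.951 CPM, also when adjusted over the list alone (median 3.53, adjusted p = 3.24e-06, and adjusted p = 0.135 with an estimated correlation). COL3A1 (ENSG00000168542, chromosome 2, 188974320 to 189012746), a fibrillar collagen, rose from 0.504 ± 0.0313 to 2172 ± 116 CPM (12.05, adjusted p = 2.59e-15). Extravillous trophoblast genes, of the invasive placental lineage, had 10 higher and 2 lower of 20 (adjusted p = 0.159, and 0.000308 with DESeq2). FN1 rose 23.0-fold to 2520 ± 419 CPM and the VEGF receptor FLT1 fell from 159 ± 0.433 to 19.4 ± 0.392. Camera called none of the germ layer lists: mesoderm had 5 higher and 3 lower of 9 (adjusted p = 0.511), endoderm 3 and 4 of 10 (0.655), and neural ectoderm 4 and 7 of 12 (0.393). Fry, which asks only whether the genes of a list move on balance in a single direction, called mesoderm (0.00196) and neural ectoderm (0.00416) and not endoderm (0.119). SNAI2 rose from 0.505 to 71.3 CPM and KDR fell from 219 to 0.889 CPM. The counts of these 4 lists were the same adjusted over the list alone.

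Cell cycle genes fell together, 30 of 32 with none higher, also when adjusted over the list alone (median -1.31, adjusted p = 6.24e-08, and adjusted p = 0.366 with an estimated correlation). MCM5, part of the replicative helicase, fell 6.13-fold from 322 ± 3.92 to 52.4 ± 3.60 CPM (-2.62, SE 0.11, adjusted p = 1.24e-10). The list of p53 targets and cell cycle arrest had 12 higher, 1 lower and 4 not called of 17, also when adjusted over the list alone (median 0.92, adjusted p = 0.0111, and adjusted p = 0.231 with an estimated correlation). The inhibitor of cyclin-dependent kinases CDKN1A rose from 17.8 ± 1.20 to 273 ± 32.1 CPM and CDKN2A from 0.237 ± 0.260 to 94.7 ± 38.5. Senescence-associated secretion genes had 7 higher and 2 lower of 10, also when adjusted over the list alone (median 2.51, or 2.41 with bounds, adjusted p = 0.0302, and adjusted p = 0.231 with an estimated correlation), and without TSC replicate 2 the adjusted p was 0.052. SERPINE1, an inhibitor of plasminogen activators, rose from 4.24 ± 0.322 to 806 ± 32.8 CPM.

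Of 23 histone chaperone and H3.3 genes 20 fell and none rose, also when adjusted over the list alone (median -0.91, adjusted p = 1.04e-05, and adjusted p = 0.172 with an estimated correlation). The H3-H4 chaperone NASP fell from 888 ± 14 to 179 ± 5.74 CPM. DNA methylation genes had 1 higher and 9 lower of 11, also when adjusted over the list alone (median -0.90, adjusted p = 0.00808, and adjusted p = 0.231 with an estimated correlation). DNMT3B, a de novo methyltransferase, fell 22-fold from 1775 ± 94.0 to 80.7 ± 10.6 CPM, while the demethylase TET2 rose from 3.26 ± 0.447 to 15.1 ± 3.51. All 5 tested replication-dependent H2A genes fell, also when adjusted over the list alone (median -1.99, adjusted p = 0.0157, and adjusted p = 0.366 with an estimated correlation). These messages mostly lack a poly-A tail, so poly-A libraries capture them poorly, and the list call was lost with DESeq2 (adjusted p = 0.164). H2AC6 went from 9.20 ± 0.227 to 0.769 ± 0.0659 CPM.

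Of 22 cholesterol synthesis and uptake genes 16 rose and 2 fell, and 17 and 2 when adjusted over the list alone (median 0.86, adjusted p = 0.00423, and adjusted p = 0.366 with an estimated correlation). The synthesis enzyme MSMO1 rose from 115 ± 2.93 to 404 ± 90.1 CPM and SOAT1, which esterifies cholesterol, from 6.40 ± 1.62 to 73.2 ± 4.92. Imprinted genes, expressed from a single parental copy, had 12 higher and 4 lower of 17 (adjusted p = 0.0729, and 0.0297 with DESeq2), with H19 at 2.01 ± 0.425 CPM in ESC and 361 ± 125 in TSC. Hypoxia response genes had 5 higher and 8 lower of 15 (adjusted p = 0.398) and interferon response genes 8 and 4 of 15 (0.449). IFITM1, a membrane protein that blocks virus entry, fell from 119 ± 6.81 to 1.37 ± 0.438 CPM. Its annotated span lies inside that of IFITM2 on the same strand, and how reads over both genes were counted is not given. The counts of these 3 lists were the same adjusted over the list alone. Among the largest increases by the rule was TRIM55, a muscle ring finger protein, at 257 ± 19 CPM against no count (at least 3232-fold). Also among them were LUM, a matrix proteoglycan, at 199 ± 39.4 (at least 2505-fold) and CRH, the placental stress hormone, at 63.8 ± 26.5 (at least 803-fold). TRIM55 (chromosome 8, 66126896 to 66175487, plus strand) and CRH (66176382 to 66178725, minus strand) are neighbours. Without the strand setting, these 2 increases may not be independent.

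**Figure D2:**
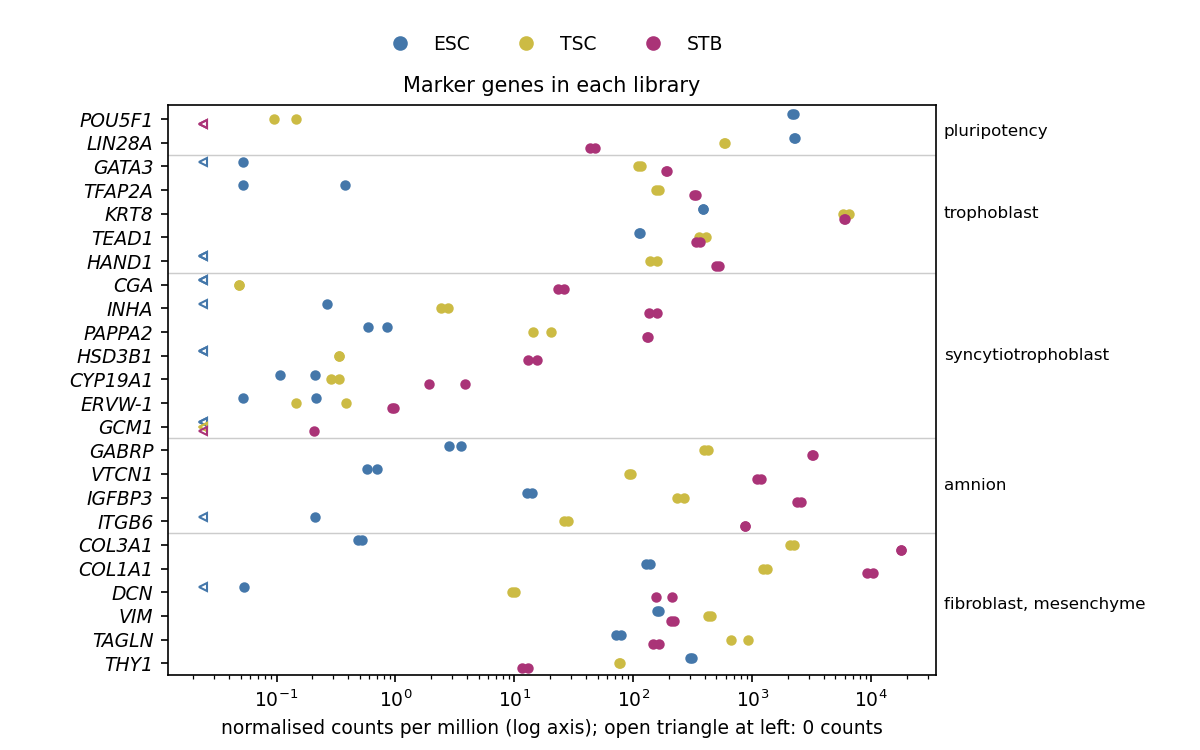
TMM-normalised CPM (log axis) of marker genes of pluripotency, trophoblast, syncytiotrophoblast, amnion and fibroblasts in the 6 libraries, some of them chosen after their values were seen. POU5F1 fell from 2203 to 0.120 CPM between ESC and TSC, while COL3A1 reached 17830 CPM in STB.

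The second comparison asked how STB differed from TSC. Most of the fibroblast and mesenchyme and amnion genes tested rose, as did some placental hormone genes. Most of the cell cycle and cholesterol genes tested fell. CGA (ENSG00000135346, chromosome 6, 87085498 to 87095406), the alpha subunit shared by chorionic gonadotropin and pituitary hormones, stood at 24.8 ± 2.0 CPM in STB against 2 counts in TSC, a ratio of 516 (95% counting interval 142 to 4270). INHA, the inhibin alpha subunit, rose 56.4-fold from 2.60 ± 0.265 to 147 ± 15.1 CPM (log2 fold change 5.82, SE 0.22, adjusted p = 2.42e-10). COL3A1 rose 8.21-fold from 2172 ± 116 to 17830 ± 9.25 CPM (3.04, SE 0.09, adjusted p = 3.80e-11). HMGCS1, an early enzyme of cholesterol synthesis, fell 6.78-fold from 705 ± 116 to 104 ± 14.8 CPM (-2.76, SE 0.14, adjusted p = 1.97e-09).

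Of 18036 genes, 4109 were higher and 5065 lower in STB, 50.86% in all, and 2118 and 2475 with at least a 2-fold change. In simulated data 17360 genes were fitted, with as many changed as before. Of those changed 1.5-fold 34.3% were recovered, and of those changed 2-fold 91.0%. There were 10 false calls, or 6.25% of calls, again above the threshold of 0.05. The limits of the first simulation hold here too. Higher genes were 44.79% of calls with TMM scaling and 36.23% with total counts only, where the median of all genes moved from -0.05 to -0.18 on the log2 scale.

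The syncytiotrophoblast list had 13 higher, 5 lower and 7 not called of 25, and 16 and 5 when adjusted over the list alone (median 0.91, adjusted p = 0.0152, and adjusted p = 0.231 with an estimated correlation). PAPPA2, a placental protease, rose 7.60-fold from 17.3 ± 4.20 to 131 ± 2.89 CPM (2.93, SE 0.17, adjusted p = 7.73e-09). PGF, placental growth factor, fell from 12.8 ± 2.35 to 1.76 ± 0.241 CPM. Several classical genes of this cell type stayed low, and these were named after their values were seen. The 2 STB libraries held 3 counts in all of GCM1, the fusion transcription factor, or 0.103 CPM. The envelope gene of fusion ERVFRD-1 was at 0.964 and 0.529 CPM and CSH1, placental lactogen, had no count, where 3 counts would be 0.101 CPM. The handling of reads with several matches is not given in the sources used here, so levels of the CGB, CSH, PSG and ERV families, which have near-identical copies, are uncertain. None of the 3 tested pregnancy-specific glycoproteins was called, also when adjusted over the list alone.

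Of 28 trophoblast stem cell and cytotrophoblast genes 13 rose and 9 fell, and 15 and 9 when adjusted over the list alone (median 0.31, adjusted p = 0.393). ITGA6, a laminin receptor of cytotrophoblast, fell 6.04-fold from 303 ± 28.2 to 50.1 ± 2.19 CPM, and PEG10, an imprinted gene of placental growth, from 1298 ± 213 to 294 ± 23.9. In the core and primed pluripotency list 2 rose, 13 fell and 13 were not called, also when adjusted over the list alone (median -1.69, or -0.40 with bounds, adjusted p = 0.0148, and adjusted p = 0.231 with an estimated correlation). LIN28A, which blocks let-7 microRNA, fell 12.9-fold from 585 ± 2.38 to 45.5 ± 2.73 CPM (-3.68, SE 0.11, adjusted p = 2.90e-11). SFRP2, a WNT modulator also made by mesenchyme, rose from 38.8 ± 3.77 to 604 ± 69.1 CPM. Naive pluripotency genes had 1 higher and 2 lower of 7, also when adjusted over the list alone (median 0.00, mean -0.86, adjusted p = 0.832).

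Amnion genes rose further, 12 higher and 4 lower of 17, also when adjusted over the list alone (median 1.51, adjusted p = 0.00206, and adjusted p = 0.231 with an estimated correlation). VTCN1, an immune checkpoint ligand, rose 12.2-fold from 93.5 ± 2.53 to 1139 ± 62.8 CPM (3.61, SE 0.11, adjusted p = 3.80e-11) and ITGB6, an epithelial integrin, 32.1-fold from 27.2 ± 1.33 to 873 ± 5.67 (5.0, SE 0.16, adjusted p = 4.03e-11), while BMP4 fell from 149 ± 0.0123 to 48.1 ± 2.09. Fibroblast and mesenchyme genes had 9 higher and 4 lower of 14, also when adjusted over the list alone (median 1.73, adjusted p = 0.0279, and adjusted p = 0.231 with an estimated correlation). Those that rose included collagens COL1A1, from 1288 ± 67.8 to 9834 ± 772 CPM, and FBLN1, from 463 ± 50.3 to 3752 ± 27.4. Those that fell were THY1, a surface marker of fibroblasts, from 76.3 to 12.3 CPM, the intermediate filament gene VIM, and the contractile genes TAGLN and ACTA2. Of the extravillous trophoblast list 13 rose and 7 fell of 20 (median 1.46, adjusted p = 0.0729, with 0.0304 for total counts only, 0.0349 for no filter on low counts and 0.000139 for DESeq2). FN1 rose 8.71-fold to 21944 ± 1900 CPM, and MMP2, a collagen-cleaving protease, from 508 ± 31.0 to 2361 ± 14.2. Mesoderm had 2 higher and 2 lower of 9 (median -0.13, adjusted p = 0.721, where the test points up), endoderm 0 and 4 of 10 (adjusted p = 0.207, and 0.0231 with only the groups compared), and neural ectoderm 1 and 6 of 12 (0.121, and 0.00242 with fry). The counts of these 4 lists were the same adjusted over the list alone. NEFL and NEFM, neurofilament genes outside these lists, fell from 58.3 ± 1.54 to 0.340 ± 0.201 CPM and from 22.7 ± 2.64 to 0.371 ± 0.0372.

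Cell cycle genes fell again, 26 of 32 with none higher, also when adjusted over the list alone (median -0.84, adjusted p = 4.83e-06, and adjusted p = 0.414 with an estimated correlation). CDC6, which licenses replication origins, fell from 64.2 ± 1.19 to 16 ± 2.94 CPM and the mitotic activator CDC20 from 107 ± 0.734 to 30.7 ± 6.99. MKI67, the proliferation marker, was named after its values were seen and had 118 ± 35.6 CPM in TSC and 66.4 ± 16.5 in STB. Of 17 genes in the list of p53 targets and cell cycle arrest 7 rose and 5 fell, and 8 and 5 when adjusted over the list alone (median -0.02, mean 0.12, adjusted p = 0.655). The growth-restraining imprinted gene CDKN1C rose from 22.8 ± 7.72 to 129 ± 9.77 CPM. Senescence-associated secretion had 2 higher and 5 lower of 10, also when adjusted over the list alone (median -2.04, adjusted p = 0.209), with SERPINE1 falling from 806 ± 32.8 to 139 ± 1.38 CPM.

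Cholesterol synthesis and uptake genes fell almost throughout, 20 of 22 with SCARB1 higher, and 20 and 2 when adjusted over the list alone (median -1.69, adjusted p = 4.81e-07, and adjusted p = 0.231 with an estimated correlation). FDPS, which makes farnesyl diphosphate, fell from 239 ± 15 to 51.9 ± 0.385 CPM and INSIG1, a sterol sensor partner, from 131 ± 12.3 to 22.5 ± 2.03. SCARB1, the receptor for high-density lipoprotein, rose from 56.6 ± 1.21 to 103 ± 9.87 CPM. Hypoxia response genes had 7 higher and 6 lower of 15 (adjusted p = 0.398, and 0.0381 with DESeq2), with the glucose transporter SLC2A1 rising 6.39-fold from 503 ± 68.6 to 3216 ± 177 CPM and the stress gene NDRG1 from 32.1 ± 3.76 to 251 ± 33.8. Imprinted genes had 7 higher and 5 lower of 17 (adjusted p = 0.2). H19, a placental non-coding RNA, rose 22.4-fold from 361 ± 125 to 8113 ± 1387 CPM (4.49, SE 0.21, adjusted p = 1.07e-09). The fetal growth factor IGF2, whose gene overlaps the INS-IGF2 readthrough gene, rose 26.6-fold from 208 ± 77.5 to 5525 ± 703 CPM (4.73, SE 0.23, adjusted p = 1.46e-09). The hypoxia and imprinted counts were the same adjusted over the list alone. Interferon response genes had 4 higher and 3 lower of 15, and 5 and 3 when adjusted over the list alone (adjusted p = 0.398), with IFITM3 rising from 55.5 ± 2.64 to 183 ± 6.08 CPM.

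Replication-dependent H2A genes had 3 higher and none lower of 5, also when adjusted over the list alone (median 2.46, adjusted p = 0.0384, and adjusted p = 0.414 with an estimated correlation). The call was lost with no filter on low counts (adjusted p = 0.196) and in 5 of the 6 fits that left out a library (0.0512 to 0.121). H2AC25 rose from 8.26 ± 3.85 to 45.6 ± 2.85 CPM. Histone chaperones and H3.3 had 1 higher and 7 lower of 23, and 1 and 6 when adjusted over the list alone (median -0.21, adjusted p = 0.266). H3-3A, encoding the replacement histone H3.3, rose from 155 ± 23.4 to 298 ± 5.79 CPM; it has many processed copies, so its level is uncertain. DNA methylation had 4 higher and 5 lower of 11, and 5 and 5 when adjusted over the list alone (median 0.12, mean -0.24, adjusted p = 0.875). DNMT3B fell from 80.7 ± 10.6 to 17.8 ± 1.18 CPM and TET3 rose from 52.2 ± 3.20 to 93.6 ± 8.21. Among the largest changes by the rule, RSPO3, a WNT amplifier, was at 20.2 ± 5.11 CPM in STB with no count in TSC (at least 279-fold), PMEPA1, a TGF-beta target, rose from 0.937 ± 0.439 to 67.5 ± 5.66, and CDH5, the endothelial cadherin, fell from 71.6 ± 8.07 to 1.39 ± 0.469.

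**Figure D3:**
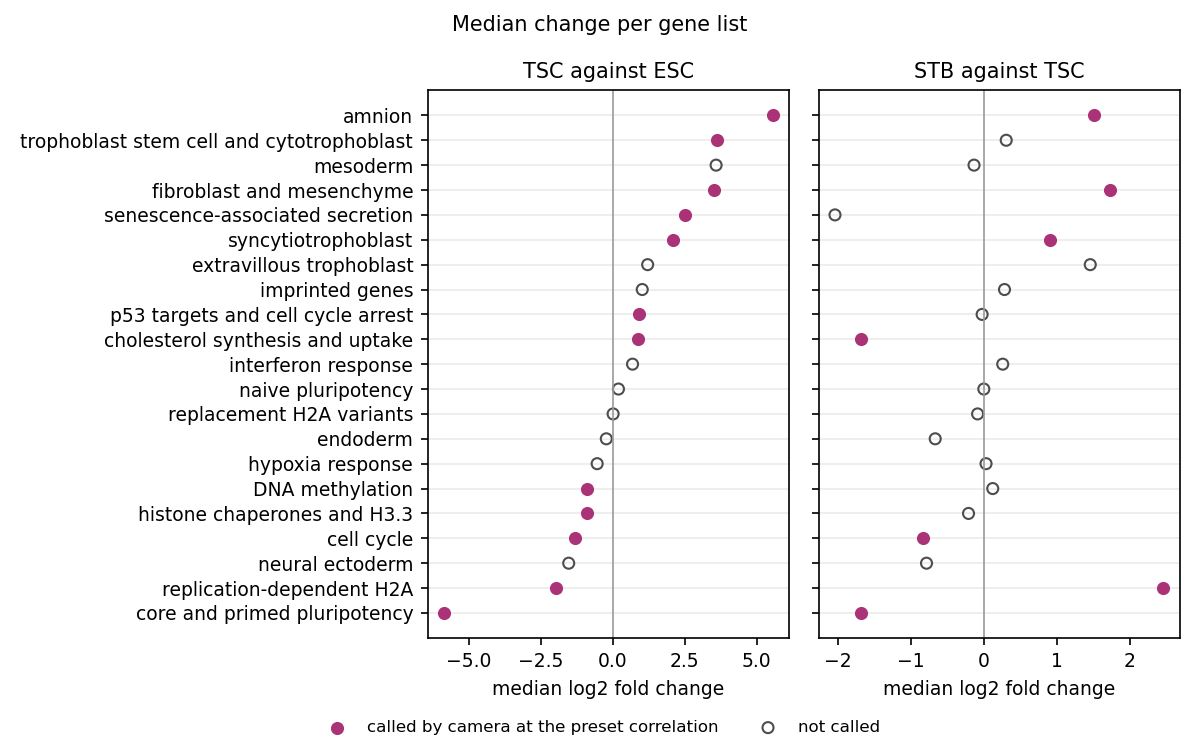
Median log2 fold change of the tested members of 21 gene lists (horizontal axis), TSC against ESC on the left and STB against TSC on the right, with filled points for lists called by camera at the preset correlation. The core and primed pluripotency list was lowest from ESC to TSC (-5.86), and the cholesterol list fell by 1.69 from TSC to STB.

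The third comparison, STB against ESC, is the sum of the other 2 and gives the whole course. Of 18036 genes, 6552 were higher and 6557 lower in STB, 72.68% in all, and 4834 and 4370 with at least a 2-fold change. POU5F1, TDGF1 and ZIC2, a primed-state transcription factor, had no count in STB, with POU5F1 at least 21760-fold lower. GABRP rose 996-fold from 3.21 ± 0.523 to 3201 ± 21.1 CPM (log2 fold change 9.96, SE 0.15, adjusted p = 8.21e-15). WNT6, a secreted WNT signal, stood at 337 ± 17.4 CPM against no count in ESC, at least 4238-fold higher.

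In the core and primed pluripotency list 27 of 28 fell (median -6.71, or -6.08 with bounds, adjusted p = 4.47e-12, and adjusted p = 0.135 with an estimated correlation). In the trophoblast stem cell and cytotrophoblast list 25 rose and 3 fell of 28 (median 3.91, adjusted p = 4.81e-07, and adjusted p = 0.135 with an estimated correlation). The syncytiotrophoblast list had 19 higher and 5 lower of 25 (median 4.69, or 4.12 with bounds, adjusted p = 0.00192, and adjusted p = 0.231 with an estimated correlation). INHBA, an activin subunit, rose from 2.25 ± 0.235 to 108 ± 0.489 CPM. Cell cycle genes fell in 31 of 32 cases (median -2.16, adjusted p = 6.53e-09, and adjusted p = 0.353 with an estimated correlation). Amnion genes had 16 higher and 1 lower of 17 (median 6.67, adjusted p = 1.68e-07, and adjusted p = 0.135 with an estimated correlation), and fibroblast and mesenchyme genes 13 higher and 1 lower of 14 (median 4.58, adjusted p = 1.04e-05, and adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone, the counts of these 6 lists were the same.

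Imprinted genes had 14 higher and 3 lower of 17 (median 1.39, adjusted p = 0.012, and adjusted p = 0.231 with an estimated correlation), with SNHG14, the host transcript of a snoRNA cluster, falling from 623 ± 8.26 to 152 ± 7.0 CPM. Histone chaperones and H3.3 had 20 lower and none higher of 23 (adjusted p = 4.54e-05, and adjusted p = 0.187 with an estimated correlation). Cholesterol synthesis and uptake had 2 higher and 16 lower of 22 (median -0.78, adjusted p = 0.0148, and adjusted p = 0.414 with an estimated correlation). DHCR24, a late reductase of the pathway, fell from 759 ± 20.9 to 224 ± 52.3 CPM. The list of p53 targets and cell cycle arrest had 11 higher and 3 lower of 17 (median 1.77, adjusted p = 0.0168, and adjusted p = 0.231 with an estimated correlation). Neural ectoderm had 2 higher and 9 lower of 12 (median -1.69, adjusted p = 0.0302, and adjusted p = 0.353 with an estimated correlation). This neural call was lost without ESC replicate 2 (0.091), without STB replicate 2 (0.0573), with a minimum mean of 1 CPM (0.107) and with DESeq2 (0.195). The extravillous trophoblast list had 13 higher and 5 lower of 20 (median 2.84, adjusted p = 0.0398, and adjusted p = 0.231 with an estimated correlation), and this call was lost without STB replicate 1 (adjusted p = 0.0505) and with a minimum mean of 1 CPM (0.0755). Adjusted over the list alone, the counts of these 6 lists were the same. The lists camera did not call were DNA methylation (2 higher and 8 lower of 11, adjusted p = 0.0537, but 0.0453 without ESC replicate 1, 0.0437 without TSC replicate 1, 0.0445 without TSC replicate 2, 0.0206 with no filter on low counts and 0.000157 with DESeq2), interferon response (8 and 2 of 15, 0.204), endoderm (1 and 6 of 10, 0.209), mesoderm (5 and 2 of 9, or 5 and 3 adjusted over the list alone, 0.537), replacement H2A variants (2 and 2 of 6, 0.598), senescence-associated secretion (5 and 4 of 10, 0.609), naive pluripotency (3 and 4 of 7, 0.609), replication-dependent H2A (2 and 2 of 5, 0.832) and hypoxia response (6 and 7 of 15, 0.986). Apart from mesoderm, their counts adjusted over the list alone were the same, and 2 of 3 pregnancy-specific glycoproteins rose.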

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

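The alternatives with GC and length offsets and without mitochondrial genes were chosen after seeing the data; the others were planned. For 252 called results of named genes, none of the values that 16 alternatives gave turned direction; 4008 were past the threshold and 18 no longer past it, and genes removed by the 1 CPM minimum or with only the groups compared gave no value there. The 6 gene counts stayed within 1.5 times under all settings except the required 2-fold change, which left 3117 genes lower in TSC than in ESC, 2118 higher and 2475 lower in STB than in TSC, and 4370 lower in STB than in ESC; a stricter requirement can only lower a count. A block for the replicate number moved 1 named gene and no list across its threshold, and replicate differences correlated between groups by -0.102 to 0.00798 across genes, which are not independent. For the other values below the cause was not tested.

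With an estimated correlation, which also cuts the test to 3 residual degrees of freedom, all 31 list calls were lost. For lists with an estimate near the preset correlation, such as pluripotency, the loss therefore cannot be put down to correlation between genes alone. For cell cycle the estimate was 0.447, and if it holds, the preset test overstates that call. For TSC against ESC the adjusted p was 0.135 for pluripotency and for trophoblast, 0.231 for syncytiotrophoblast and 0.366 for cell cycle. For STB against TSC it was 0.231 for pluripotency and for syncytiotrophoblast and 0.414 for cell cycle. For STB against ESC it was 0.135 for pluripotency and for trophoblast, 0.231 for syncytiotrophoblast and 0.353 for cell cycle. The syncytiotrophoblast call of TSC against ESC was also lost with no filter (0.0527), and ranged from 0.0119 to 0.0593 with a library left out. With fry, 22 more lists were called, and with DESeq2 5 more were called and 2 lost.

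The values that turned direction were not called in the fit as reported. With a library left out, H2AJ in TSC against ESC ranged from -0.4052 to 0.4172, called both ways. The range was -0.2216 to 0.1619 for H2AX in STB against TSC, -0.1011 to 0.007235 for H2AZ2 in TSC against ESC, and for MACROH2A1 -0.08746 to 0.2565 in TSC against ESC, -0.2907 to 0.0522 in STB against TSC and -0.09535 to 0.0142 in STB against ESC. MACROH2A1 was called without TSC replicate 2 in TSC against ESC and in STB against TSC. H2AX in STB against TSC was 0.01595 with DESeq2 size factors, 0.0122 with a 1 CPM minimum and 0.007546 with DESeq2, MACROH2A1 in STB against ESC 0.03034 with a 1 CPM minimum, and H2AZ2 in STB against TSC 0.0003396 with GC and length offsets.

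List tests that turned, given as adjusted p, were with no filter naive pluripotency in TSC against ESC (0.904), mesoderm in STB against TSC (0.986) and STB against ESC (0.922), and hypoxia in STB against ESC (0.766). With DESeq2 they were naive pluripotency (0.32) and interferon response (0.774) in TSC against ESC, and naive pluripotency (0.549) and replication-dependent H2A (0.909) in STB against ESC. With fry, it was p53 targets in STB against TSC (0.925). With a library left out the ranges were 0.706 to 0.942 for naive pluripotency in TSC against ESC, 0.58 to 0.922 for replacement H2A variants in STB against TSC and 0.832 to 0.945 for hypoxia in STB against ESC. The robust spread and the GC and length offsets were not run on lists, and pseudocount alternatives apply only to values other than counts. Depth limits genes near 3 counts per group.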

Other observations

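All gene lists in this part beyond the fixed ones were chosen after seeing the data, as were all tests below. For the 2 tests of the TSC libraries' difference and that of H2AJ, only the predictions were written before the tests were run. The patterns they address had already been seen. The added lists have no set test, and some of their genes also belong to the fixed lists. From TSC to STB the matrix genes rose widely, 23 higher and 3 lower of 30. They included COL17A1, an epithelial collagen of hemidesmosomes, from 5.02 ± 1.31 to 207 ± 3.65 CPM, COL7A1, the anchoring fibril collagen, from 71.5 ± 11.4 to 748 ± 136, and DCN, a collagen-binding proteoglycan, from 9.81 ± 0.314 to 184 ± 40. From ESC to TSC 28 of these rose and 2 fell. Feedback targets of BMP and TGF-beta had 9 higher and 6 lower of 18 from ESC to TSC, and 11 higher and 3 lower from TSC to STB. SMAD7, an inhibitor of the pathway, rose from 15.4 ± 3.80 to 77.5 ± 5.81 CPM and TGFBI from 287 ± 9.53 to 4910 ± 264, while MSX1 fell from 138 ± 33.9 to 27.6 ± 1.03.

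All 15 tested NRF2 targets, genes of the antioxidant response, were lower than in TSC (median log2 fold change -2.39), after 9 had risen and 5 fallen from ESC to TSC. NQO1, a quinone reductase, fell from 310 ± 12.1 to 34.7 ± 5.76 CPM and TXNRD1, thioredoxin reductase, from 528 ± 4.61 to 93.0 ± 7.28. Genes of amino acid synthesis and ATF4 had 22 lower and 1 higher of 25 (median -1.54), against 13 higher and 6 lower from ESC to TSC. PSAT1, of serine synthesis, fell from 402 ± 20.4 to 31.8 ± 2.05 CPM. SRF and YAP targets had 14 lower and 3 higher of 19 (median -0.89), against 15 higher and 4 lower from ESC to TSC. ANKRD1 fell from 549 ± 37.1 to 68.9 ± 11.4 CPM, while TPM1 rose from 1927 ± 29.1 to 4061 ± 217.

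The TSC libraries differed beyond counting error, with a chi-square per degree of freedom of 37.6 against 3.53 in ESC and 6.62 in STB. Mitochondrial transcripts, 2.59% and 5.29% of counts, were argued against as the whole cause, since the value without them was 24.4. Transcript GC content and length accounted for 21.4% of the variance of the TSC differences, against 0.583% in ESC and 2.39% in STB, and for 59.6%, 5.15% and 14.1% in TSC, ESC and STB among the 9978 genes above 10 CPM, so a difference in library preparation or RNA quality may contribute. H2AJ, whose transcript has 62.9% GC, differed by 0.81 on the log2 scale, and 53.3% of that was left after GC and length offsets, with a counting error of 10.3 points around a bound of 50%, so this share cannot be told apart from either side of the bound. A difference between the cultures stays open and was not tested.

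Of 25 syncytiotrophoblast genes with no near-identical copy, 13 were below 10 CPM in STB (median 8.46 CPM). Another 11 stood above 20 CPM, against 8 in TSC, with INHA highest at 147. The set was chosen to leave out near-identical copies, so reads shared between copies are no candidate cause for it. CPM is scaled to library totals, and 3 counts correspond to 0.101 CPM, far below the median. This argues against sequencing depth for the set's median, but not for single members near 3 counts. For the CGB, CSH, GH2 and PSG families, 11 of 20 members had no count, and loss of shared reads cannot be told apart from absence, since the table does not hold such reads. A candidate explanation is an amnion-like programme: 15 of 18 amnion genes were above 20 CPM in STB and 13 already in TSC, and the rise of that list's median from TSC lay at percentile 100 of 10000 random lists matched on expression. Random lists ignore correlation between genes. With an estimated correlation of 0.0229 and 3 residual degrees of freedom, the camera adjusted p of the amnion list was 0.231. The syncytiotrophoblast list lay at percentile 99.99, so the random-list test does not separate the programmes. Its criterion was made stricter after these values were seen. The programmes stay open, as does the efficiency of the differentiation.

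COL3A1, COL1A1 and other collagen genes rose from TSC to STB, while COL6A1 fell and COL6A2 was not called. The smallest log2 fold change of COL3A1, COL1A1 and FN1 was 2.8 over 3 scalings. These scalings kept the median of all genes between -0.181 (total counts only) and 5.13e-15 (DESeq2 size factors), too close to undo such a rise. The rise therefore did not rest on the choice among these 3, and scaling beyond them was not tested. Of the 14 tested fibroblast and mesenchyme genes 9 rose and 4 fell. Those 4 (THY1, VIM, TAGLN and ACTA2) already stood at 76.3, 440, 792 and 90.5 CPM in TSC, and a fall from such levels can hide RNA of added cells, so fibroblasts or mesenchymal cells among the STB cells cannot be told apart from a change within the TSC-derived cells. No other test of the source was run.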
